A study of Zea mays with 18 samples.

How the data were processed

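The measurements are 2-colour hybridizations of maize leaf RNA to a maize long-oligonucleotide array. The series holds 18 records, each the sample of 1 channel of 1 of 9 arrays, and describes 9 plots, 3 on the backslope (site code 3014) and 6 on the summit/shoulder (site codes 13013 and 306), all of 1 field. Plots are the replicates, each with RNA pooled from 4 plants, and the 2 hybridizations of a plot are technical. All 3 backslope plots carry 1 site code, so the position class cannot be told apart from what that code stands for. Groups were taken from the labels alone. Loop 1 held backslope plot 1 with summit/shoulder plots 1 and 4, loop 2 backslope plot 2 with plots 2 and 5, and loop 3 backslope plot 3 with plots 3 and 6, where plots 1 to 3 carry code 13013 and plots 4 to 6 code 306. Loop 3 was scanned apart from loops 1 and 2. Its plot codes also all end in E, while those of loops 1 and 2 end in B and a number, so the 2 cannot be told apart. The loop term takes up a shift common to the plots of a loop, but not a position difference that itself differs in loop 3.

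Per the file headers, the spot values are scan intensity from GenePix Pro 6.0 and a 4000B scanner at 635 nm (red) and 532 nm (green), as median foreground and median local background of each spot, with no normalization. The authors also gave a table of 1 score per spot and sample. Each deposited score column covers 14976 of 46128 spots (32.5%). On 7 arrays it matches the z-score of the log foreground of 1 scan, without background subtraction, to a median absolute difference of at most 1.9e-05. On arrays 3 and 9 the match is less close. What set these spots apart is not given in the sources used here. The column medians of the score ran from -0.31 to -0.22.

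The score columns settled which scan a titled sample has in the authors' own table. Samples titled R follow the 532 nm scan and samples titled B the 635 nm scan, with r of 1 across spots on 7 arrays and 0.996 and 0.999 on arrays 3 and 9, while spots are not independent replicates. The dye label of samples titled R is Alexa 647, the dye read at 635 nm, and the source name of each record is the other sample of its array. The values reported take R as 532 nm and B as 635 nm, which is likely and not certain. The design of the tests, fixed before the data were examined, had assumed the other assignment. For values from log ratios, that assignment turns every sign of a comparison and leaves every p as it is. Single-channel values also hold the mean intensity of each array, so results from them would change by more than the sign, which was not run.

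On array 6 the probe names of 2676 spots in blocks 45 to 47 are shifted against the other arrays. Across those spots the intensities correlate with array 1 at r = 0.0686 by position and at 0.825 by probe name, so all arrays were joined by probe name. The score table, joined by position, has 788 valued spots there.

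Intensities were background-corrected by normexp with an offset of 50, and log ratios were normalized by loess within each array in limma 3.58.1 (R 4.3.3, statmod 1.5.0). Spots marked bad (-100) were left out, as were 2592 control or empty spots, and spots of 1 probe were averaged. A probe was kept when its foreground exceeded the background by 2 background SDs in either scan on at least 5 of 9 arrays and when at least 2 loops were complete, which left 26777 of 43393 probes, 23406 of them with 3 complete loops. Median foreground per array ran from 220 to 359 at 635 nm and from 199 to 386 at 532 nm. An annotation existed for 21706 of the tested probes (81.1%). The gene table provided as a reference matched 6 transcript accessions of the array and 0 of its protein hits, so genes are named by the array's own annotation.

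Since each plot was labelled once with each dye within its loop of 3 arrays, the value of a plot relative to its loop mean is its log ratio where it was read at 635 nm minus its log ratio where it was read at 532 nm, over 3, and a dye effect common to the arrays cancels. The 9 values per probe were fitted in limma with loop and group as terms and moderated variances, with 5 residual degrees of freedom (4 with site codes), and p was adjusted by Benjamini and Hochberg with a threshold of 0.05. The dye effect itself was tested in limma as the intercept of the log ratios of the 9 arrays beside a group term. There 601 probes were higher and 1956 lower in the 635 nm scan, with arrays that share plots taken as independent. The likeness of plots by loop was described on single-channel values as correlations across probes of deviations from group means, whose probes are not independent. Plots of different groups correlated at 0.227 to 0.774 within a loop (6 pairs, median 0.423) and at -0.555 to 0.236 between loops (12 pairs, median -0.258). Centring on group means pushes the values between loops below 0, and plots of a loop shared arrays. The values therefore cannot tell a likeness of the plots from that of the arrays. The steps after normalization were tested on simulated log ratios with 100 changed probes of each size in 20 sets of 26777 probes. Background correction, loess and the filter were not part of it. Each probe had equal noise in every plot, with variances taken from the fit, so the rates need not hold in these data. A log2 difference of 1 was recovered at 84.2% of changed probes, a difference of 2 at 98.4%, and 5.54% of the calls were false. A shift of 0.25 put into the light-reaction list was called in 20 of 20 sets, with 0.05 calls per set among 30 other lists. Simulated probes varied independently of one another. In the data the estimated correlation was 0.0301 within the light-reaction list and 0.103 within the ribosomal protein list. The simulation therefore does not give the rate of false list calls in these data.

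Gene lists of 32 kinds were written as patterns on annotation words before the data were examined, and 31 had at least 5 measured genes. They were tested with camera on limma's moderated statistics, with the brightest probe per gene among 18565 genes and a preset correlation of 0.01, adjusted over the 31 lists. They were tested again with a correlation estimated from the residuals, on genes measured in all plots. That run also rests on the 5 residual degrees of freedom, so its larger p cannot be put down to the correlation alone. After their values were seen, 119 members matched only inside another word or accession were left out of 9 lists. Lists overlap and hold genes that leaves express in general, so a marker list does not measure a cell number.

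Named genes were chosen by a rule fixed before the data were examined. It takes probes with 1 gene name or description past the threshold with 1 sign in all complete loops, the 10 with the largest log2 difference per direction and 1 probe per gene. Where fewer than 10 passed, the rest were filled in by smallest p among probes with a log2 difference of at least 0.5 and are given as values. Labels that give only a clone, a locus or an unknown or hypothetical protein were not taken as names, a reading that the fixed rule does not spell out and that leaves out 11 called probes higher and 23 lower. In each list it takes up to 3 genes with the smallest p, of which the report gives the first or all. For the site codes it takes up to 5 genes per direction past the threshold, of which there were none.

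Alternatives tried were no background subtraction, an offset of 0, print-tip loess, median centring of each array, no filter and a strict filter on dim probes, all negative spot marks left out, array-level log ratios, single-channel values with and without the loop as a block, the authors' scores, trended and robust variances, sample weights, an adjusted p threshold of 0.10, each plot and each loop left out, each loop alone, all probes of a list and an estimated correlation. Added after seeing the data were gene lists with no member left out and the shifted probes of array 6 left out. Leaving out a plot drops its value, while the values of its loop still come from the same 3 arrays. Leaving out a backslope plot takes its whole loop out of the position contrast, and a probe with 2 complete loops can then rest on 1. For explanations, lists were compared with 10000 random lists matched on intensity, and groups were reassigned among plots. With 1 plot of each loop set apart, the position contrast cancels where 1 of the 3 is a backslope plot, and part of it stays where 0 or 2 are. Where it cancels, a difference by position goes into the residual, which can raise p. Reads, raw images and a genome reference were not used here.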

Results

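Leaves of field-grown maize were compared between 3 plots on a backslope, which the series title calls well hydrated, and 6 plots on the summit and shoulder of the same field, which it calls drought stressed. Each plot gave 1 RNA sample pooled from 4 plants, taken from the upper 8 cm of the topmost leaf that was fully expanded, on the day after an evening thunderstorm. The summit/shoulder plots carried 2 site codes, 13013 and 306, with 3 plots each, and the 3 backslope plots all carried another. A difference between position classes therefore cannot be told apart from what is particular to the backslope code. Neither the meaning of the codes nor the time of day at which each plot was collected is given in the sources used here. RNA of every plot was hybridized 2 times, once in each dye, on 9 long-oligonucleotide arrays of 2 colours. The arrays formed 3 loops of 3 arrays, and every loop held 1 backslope plot and 2 summit/shoulder plots. Between 29.9% and 57.7% of the array's probes stood above background in the red scan and between 53.2% and 78.4% in the green scan. After filtering, 26777 probes were tested. The number of arrays limits the precision of every value.

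The comparison of position classes asked which leaf transcripts differ between plants of the summit/shoulder and plants of the backslope. The thiazole biosynthetic enzyme, which makes the thiazole ring of vitamin B1 in the chloroplast, was higher on the summit/shoulder. Its form 1-2 (MZ00035698, chromosome 3) was 6.46-fold higher (log2 2.69, SE 0.26, adjusted p = 0.0207) in 4 of 4 plots measured, those of loops 1 and 2. Its form 1-1 (MZ00015318) was 2.21-fold higher (log2 1.14, SE 0.14, adjusted p = 0.0208) in 6 of 6 plots. Plots of a loop are set against the same backslope plot, so such counts do not stand for independent comparisons. Zinc finger transcription factor ZF1 (MZ00056566) was lower (log2 -2.33, SE 0.30, adjusted p = 0.0256) in 6 of 6 plots, although 1 of its 2 other probes lay on the other side. It was above background in 8 of 12 summit/shoulder hybridizations, so the size is uncertain, at -2.08 with no background subtraction and -2.56 with an offset of 0. The calcium-binding protein CCD1 (MZ00016998) was 4.65-fold lower (log2 -2.22, SE 0.32, adjusted p = 0.0344), again in 6 of 6 plots. Chromosomes are those of the array annotation, whose genome build and positions are not given in the sources used here. The direction is likely and not certain. It follows the authors' value table, in which the samples titled R follow the green scan and those titled B the red scan, very closely on 7 arrays and less closely on arrays 3 and 9. The labels alone do not settle it. Titles read with the dye labels place the samples titled R in the red scan, and source names read with the dye labels place the other sample of the array there. The design of the tests had assumed the reading by titles and dye labels before the data were examined. Under it every sign in the comparisons on log ratios turns and the counts swap, so that 66 probes are higher and 29 lower.

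With the likely direction, 4 further genes with a descriptive name, all enzymes, passed the test on the higher side. The H isozyme of alpha 1,4-glucan phosphorylase (MZ00015640), which releases glucose 1-phosphate from glucans, was 2.12-fold higher (log2 1.08, SE 0.16, adjusted p = 0.0381). A methyltransferase of the Rubisco small subunit (MZ00021829) was 2.01-fold higher (log2 1.01, SE 0.11, adjusted p = 0.015). Inorganic diphosphatase (MZ00023951), which splits pyrophosphate, had a log2 difference of 0.88 (SE 0.14, adjusted p = 0.048), although only 3 of its 7 other probes had that direction. Argininosuccinate lyase (MZ00013404), of arginine synthesis, had a log2 difference of 0.77 (SE 0.12, adjusted p = 0.0461). Among the probes called higher, 11 more carry only a clone, locus, unknown or hypothetical label and are not named by rule. Of these, the F16L1.3 protein (MZ00022804) at log2 2.53 and AT3g20810 (MZ00030647) at 0.94 are given here by choice after their values were seen. The 4 genes that the rule fills in on the higher side did not pass. A ribonucleoprotein stood at log2 0.73 (adjusted p = 0.0589) and the Cinful1 polyprotein of a retrotransposon at 1.26 (0.0607). A chloroplast RNA processing protein stood at 0.70 (0.0627) and an RNA helicase at 0.98 (0.063).

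On the lower side, phosphoadenylyl-sulfate reductase (MZ00042096, chromosome 7), of sulfate assimilation, was 4.26-fold lower (log2 -2.09, SE 0.33, adjusted p = 0.048). It stood at -2.58 and -2.82 in loops 1 and 2, at -0.87 in loop 3 and at -2.70 without backslope plot 3. Ethylene responsive element binding factor3 (MZ00026596), a transcription factor of the AP2/ERF family, was 4.03-fold lower (log2 -2.01, SE 0.30, adjusted p = 0.0386), with 1 of its 2 other probes on the other side. An EREBP-like protein (MZ00018541) of the same family was 2.85-fold lower (log2 -1.51, SE 0.24, adjusted p = 0.0492). Glutathione S-transferase GST 24 (MZ00042425), which couples glutathione to reactive compounds, was 3.68-fold lower (log2 -1.88, SE 0.19, adjusted p = 0.015). Another probe of it (MZ00042426) was lower as well, at log2 -1.01, but above background in 7 of 12 summit/shoulder hybridizations, so its size is uncertain. In summit/shoulder plot 6 the first of these probes stood at -1.18, apart from -2.30 to -1.89 in the other 5 plots. A selenium-binding protein (MZ00032261) was 3.62-fold lower (log2 -1.86, SE 0.26, adjusted p = 0.0335). A multiple stress-associated zinc-finger protein (MZ00044463) was 3.02-fold lower (log2 -1.59, SE 0.24, adjusted p = 0.0386). These 6 genes were lower in 6 of 6 plots. Probes for ribosomal protein S4 (MZ00040988, log2 -2.56, SE 0.32) and the DNA repair helicase XP-D (MZ00030787, log2 -2.53, SE 0.32) were lower in 4 of 4 plots measured, both at an adjusted p of 0.0386. Of 5 other probes annotated as the same S4 protein, 0 had that direction. The S4 probe was above background in 8 of 12 and the XP-D probe in 6 of 12 summit/shoulder hybridizations, so the sizes of both differences are uncertain.

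**Figure D1:**
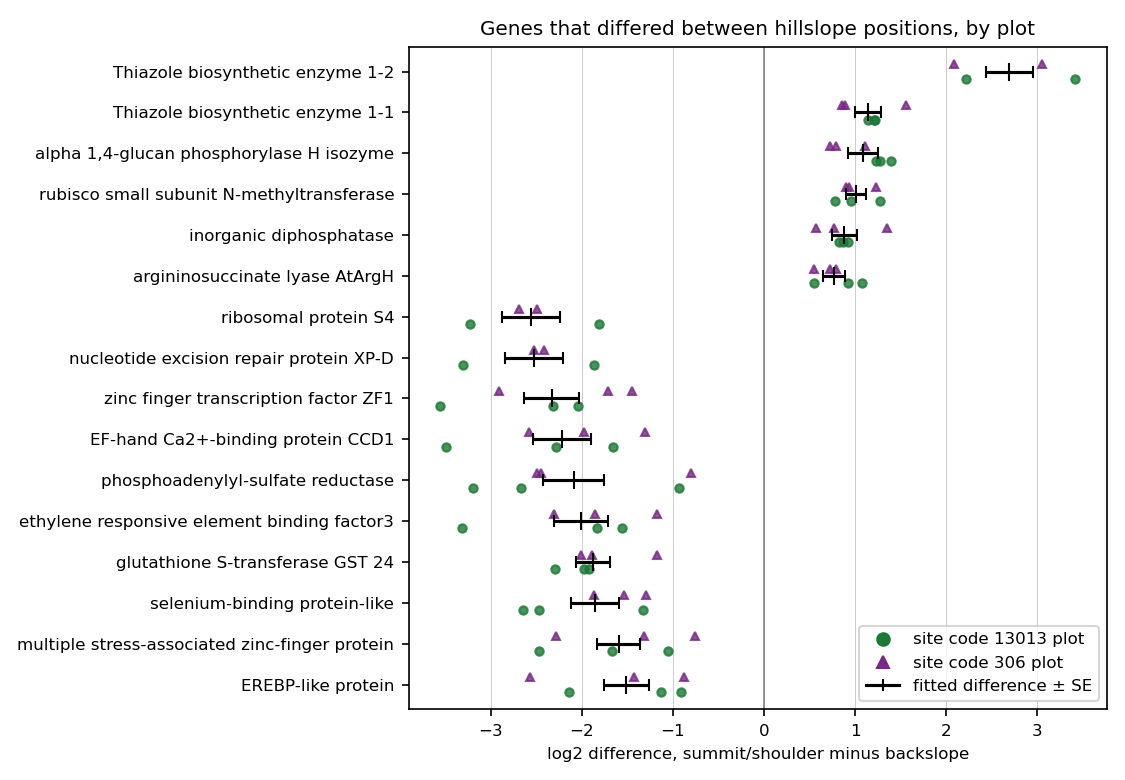
Log2 difference between summit/shoulder and backslope for the 16 genes named by rule that passed the test; points are single plots minus the backslope plot of their loop (circles site code 13013, triangles site code 306) with bars for the fitted difference ± SE. Every plotted point lies on the side of its fitted difference, from 2.69 for thiazole biosynthetic enzyme 1-2 to -2.56 for the ribosomal protein S4 probe, and every sign turns under the other reading of the labels. Points of a loop share a backslope plot, and the genes were chosen with the same sign in all complete loops, so the shared side is no independent check.

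In total 95 of 26777 probes passed an adjusted p of 0.05 in limma with the loop as a block, 29 higher and 66 lower on the summit/shoulder (n = 6 and 3 plots). Of these, 71 carry an annotation. The median absolute log2 difference of the 95 was 1.34, and all 95 had the same sign in every loop in which they were complete. At an unadjusted p under 0.05 there were 1719 probes higher and 1719 lower, where chance gives 1339 in all. Centring each array on its median in place of loess gave 40 higher and 32 lower, and 2355 higher and 1186 lower at an unadjusted p under 0.05, so the balance of directions depends on the normalization. The count rested on single plots, and without a backslope plot its whole loop leaves the position contrast. It was 0 without backslope plot 1 (2107 unadjusted), 0 without backslope plot 2 (2542 unadjusted) and 168 without backslope plot 3. It was 1 without summit/shoulder plot 1, 35 without plot 2, 16 without plot 4 and 389 without plot 5. Within single loops it was 209 in loop 1, 63 in loop 2 and 0 in loop 3 (1349 unadjusted), with the lone backslope plot of a loop assumed to vary like the others. Of the 23 named genes that passed over all loops, 10 passed within loop 1 and 7 within loop 2, and 0 of 20 within loop 3. Each of the 23 kept its sign without any 1 plot, which for a backslope plot follows from the same sign in every complete loop. Of the 23, 0 passed without backslope plot 1, backslope plot 2 or summit/shoulder plot 1, 1 passed without plot 4, 7 without plot 2, 10 without backslope plot 3, 15 without plot 3, 20 without plot 6 and 23 without plot 5.

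Transcripts of the photosynthetic light reactions, which cover antenna proteins, photosystems and electron carriers, were lower on the summit/shoulder as a list. The median log2 difference of 78 genes was -0.23, and 61 lay below 0. A type II chlorophyll a/b binding protein of photosystem II (MZ00034931) was 1.88-fold lower (log2 -0.91, SE 0.12, adjusted p = 0.0259). Another chlorophyll a/b binding protein (MZ00037091) was 1.65-fold lower (log2 -0.72, SE 0.11, adjusted p = 0.0447), both in 6 of 6 plots. A further one (MZ00023546) stood at log2 -1.11 without passing (adjusted p = 0.0507). Of the members, 2 were lower over all probes and 9 lower when adjusted over the list alone. The list passed camera with its preset correlation of 0.01 (adjusted p = 2.09e-07 over 31 lists), but not otherwise: adjusted p = 0.242 with an estimated correlation (unadjusted p = 0.0078, 72 genes). Its medians within the 3 loops were -0.13, -0.30 and -0.32. Of 27 ways of setting 1 plot of each loop apart, 2 including the true one gave a p as small. Of the 12 in which the position contrast cancels, 0 gave one under 0.05, but there a position difference adds to the residual and can raise p.

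Carbon fixation transcripts showed no such shift, with a median of 0.0036 over 35 genes (adjusted p = 0.852). Their 1 called member over all probes, and 1 adjusted over the list alone, was the methyltransferase of the Rubisco small subunit, which modifies proteins and does not itself fix carbon. Phosphoenolpyruvate carboxylase, the first enzyme of C4 fixation, stood at log2 0.43 (SE 0.11, adjusted p = 0.153). The spot of the Rubisco large chain was saturated on 5 arrays, which compresses a difference, so neither its size nor its failure to pass can be read. Bundle sheath markers had a median of -0.14 over 8 genes (adjusted p = 0.43) with no member at an unadjusted p under 0.05. Mesophyll markers had a median of 0.16 over 11 genes (adjusted p = 0.43). In limma 0 members passed over all probes, 1 was higher when adjusted over the list alone and 2 at an unadjusted p under 0.05. Chloroplast-encoded transcripts had a median of -0.16 over 6 genes (adjusted p = 0.846), none at an unadjusted p under 0.05.

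Ribosomal protein transcripts of the cytosol and plastid were higher as a list by a small amount. Their median log2 difference was 0.22 over 244 genes, and 196 lay above 0. No single gene passed over all probes or adjusted over the list alone in limma, with 68 higher and 6 lower at an unadjusted p under 0.05. The S4 probe above was not the probe that stood for its gene. A ribosomal protein (MZ00043074) stood at log2 0.60 (adjusted p = 0.0954), while the plastid ribosomal protein L19 stood at -1.28 (adjusted p = 0.0635) and a 60S ribosomal protein at -0.63 (adjusted p = 0.0793). The list's adjusted p was 3.54e-11 in camera with the preset correlation, and adjusted p = 0.627 with an estimated correlation (unadjusted p = 0.0405, 233 genes). Its medians within the loops were 0.20, 0.24 and 0.23, and 2 of the 27 ways of setting 1 plot of each loop apart, the true one included, gave a p as small. Of the 12 in which the position contrast cancels, 8 gave one under 0.05.

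Transcripts of phosphate uptake and starvation were lower as a list, with a median of -0.19 over 22 genes, 18 of them below 0 (adjusted p = 0.0111; adjusted p = 0.777 with an estimated correlation). No member passed over all probes in limma, 3 were lower when adjusted over the list alone and 5 at an unadjusted p under 0.05. Phosphate-induced protein 1, named for its induction by phosphate in cultured cells, stood at log2 -1.16 (adjusted p = 0.0962). A purple acid phosphatase stood at -0.42 (0.176) and another acid phosphatase at -0.43 (0.179), enzymes that release phosphate from organic esters. The list did not pass without backslope plot 2 (adjusted p = 0.115) or with both channels required above background on all 9 arrays (0.397). Within the loops its medians were -0.18, -0.22 and -0.10, and the p in loop 3 (0.264) rests on 1 backslope plot. Its median was -0.12 without summit/shoulder plot 4 and -0.096 with no filter on dim probes.

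Phenylpropanoid and flavonoid transcripts, of lignin and pigment synthesis, were slightly lower as a list. Their median was close to 0, at -0.071 over 85 genes, 54 of them below 0 (adjusted p = 0.0401; adjusted p = 0.845 with an estimated correlation). No member passed over all probes or adjusted over the list alone in limma, and 11 were lower at an unadjusted p under 0.05. Cinnamyl alcohol dehydrogenase stood at log2 -1.58 (adjusted p = 0.0927), an anthocyanin 5-O-glucosyltransferase at -1.52 (0.103) and cinnamoyl CoA reductase at -0.81 (0.112). The glucosyltransferase stood at -2.12 without backslope plot 1 and -0.92 without backslope plot 2, each from a single loop. With median centring of each array, which moved the median of all probes from 0.0066 to 0.043, the list stood at -0.020 and still passed (adjusted p = 0.0402). The median was -0.036 with both channels required above background and -0.011 with the authors' scores. The list no longer passed without backslope plot 2 (adjusted p = 0.153) or 3 (0.0861), without summit/shoulder plot 2 (0.107), 3 (0.123) or 4 (0.0975). Within the loops its medians were -0.052, -0.090 and -0.097, and the p there (0.382, 0.0718 and 0.296) rests on 1 backslope plot each and says nothing about stability.

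**Figure D2:**
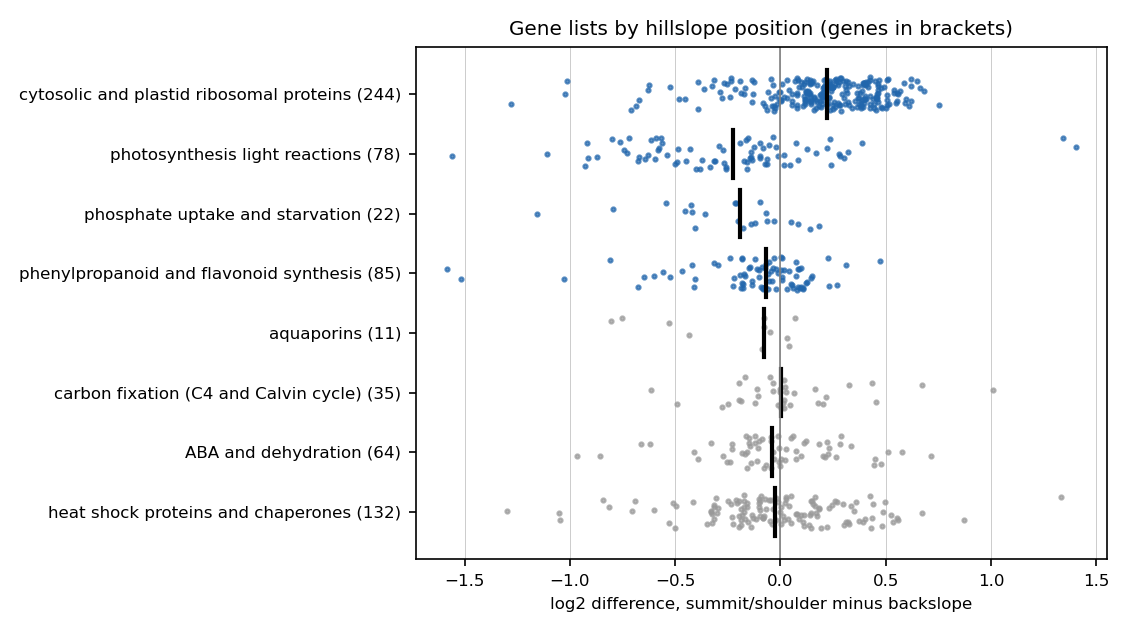
Log2 difference between summit/shoulder and backslope for each gene (point) of 8 fixed gene lists, with the number of genes in brackets and a black bar at the median; blue lists passed the test with the preset correlation and grey lists did not. The medians run from 0.22 for ribosomal proteins to -0.23 for light reactions, whose calls ended with an estimated correlation, and every sign turns under the other reading of the labels.

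Gene lists of water and heat stress did not pass. Aquaporins, the water channels, had a median of -0.080 over 11 genes (adjusted p = 0.108). In limma 0 of them passed over all probes, 2 were lower when adjusted over the list alone and 4 at an unadjusted p under 0.05. NIP2-2 stood at log2 -0.53 (adjusted p = 0.127), a plasma membrane intrinsic protein at -0.81 (0.181) and a further aquaporin at -0.75 (0.261). The last was -0.28 without backslope plot 2 and -1.22 without backslope plot 3, each from a single loop. Abscisic acid and dehydration genes had a median of -0.040 over 64 genes (adjusted p = 0.846). In limma 0 of them passed over all probes, 2 were higher and 2 lower when adjusted over the list alone, and 5 higher and 5 lower unadjusted. A protein phosphatase 2C, a class that holds repressors of abscisic acid signalling, stood at -0.97 (adjusted p = 0.0529). An abscisic acid-induced protein stood at -0.66 (0.0948) and an abscisic acid inducible gene at 0.58 (0.107).

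Heat shock proteins and chaperones had a median of -0.028 over 132 genes (adjusted p = 0.852). A heat shock factor (MZ00019326, chromosome 7) was lower (log2 -1.05, SE 0.16, adjusted p = 0.0434) in 6 of 6 plots. It was above background in 6 of 12 summit/shoulder and 6 of 6 backslope hybridizations, so the size is uncertain, at -0.91 with no background subtraction and -1.31 with an offset of 0. It was the 1 member that passed, over all probes and adjusted over the list alone. A chaperonin stood at log2 1.33 (0.128) and a heat shock protein at -1.05 (0.132). Osmolyte genes had a median of -0.043 over 22 genes (adjusted p = 0.852). In limma 0 of them passed over all probes, and 1 was higher and 2 lower both when adjusted over the list alone and unadjusted. Proline oxidase, which degrades proline, stood at -1.01 (adjusted p = 0.0644), and pyrroline-5-carboxylate synthetase, which makes it, at 0.48 (0.14). A trehalose 6-phosphate synthase stood at -0.77 (0.181), and at -0.43 without backslope plot 1, from a single loop.

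Ubiquitin-conjugating enzyme UBC5a (MZ00041062), of general protein turnover, was 2.12-fold lower (log2 -1.09, SE 0.15, adjusted p = 0.0324). It was the 1 member of senescence and proteolysis to pass, over all probes and adjusted over the list alone (170 genes, median -0.012, adjusted p = 0.683). An auxin-induced protein (MZ00043103) was 2.84-fold lower (log2 -1.50, SE 0.23, adjusted p = 0.0389), while the 1 other probe of that gene lay on the other side. It was the 1 member of the auxin list to pass in both adjustments (75 genes, median -0.024, adjusted p = 0.43). A called probe of another auxin-induced protein (MZ00056828, log2 -1.08, adjusted p = 0.0386, chosen after its values were seen) is not counted, since a brighter probe stands for that gene. GST 24 was the 1 of 112 antioxidant and detoxification genes called over all probes, with 3 lower when adjusted over the list alone (median 0.0093, mean -0.0033, tested higher, adjusted p = 0.846). Transposons and repeats had 2 members lower over all probes, and 1 higher and 3 lower when adjusted over the list alone (75 genes, median 0.011, mean -0.014, tested lower, adjusted p = 0.906). The 2 members were a copia protein at log2 -0.81 (SE 0.13, adjusted p = 0.048) and an activator-like element at -0.96 (SE 0.15, adjusted p = 0.048). Copia was above background in 4 of 12 summit/shoulder and 4 of 6 backslope hybridizations and the activator-like element in 8 of 12 and 5 of 6, so both sizes are uncertain. With no background subtraction copia stood at -0.53 and no longer passed, and with an offset of 0 it stood at -1.25 and the activator-like element at -1.27, which then no longer passed. In UBC5a, the auxin-induced protein, copia and the activator-like element the difference had 1 sign in 6 of 6 plots. Circadian clock and photoperiod genes had a median of 0.044 and a mean of -0.036 over 25 genes and were tested higher (adjusted p = 0.846). In limma 0 of them passed over all probes, 2 were higher and 1 lower when adjusted over the list alone, and 4 higher and 4 lower unadjusted. Each gene counts through its brightest probe, so an LHY probe that passed (MZ00014272, log2 -1.26, adjusted p = 0.0413, chosen after its values were seen) is not among them. CONSTANS-like CO8 stood at log2 -1.39 (adjusted p = 0.0589), pseudo-response regulator 1 at 0.68 (0.107) and gigantea at 0.44 (0.152).

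In the lists that follow, no member passed in limma over all probes or adjusted over the list alone. The counts given are those at an unadjusted p under 0.05, and the gene named is the member with the smallest p. Jasmonate and wounding genes had a median of -0.080 over 34 genes (adjusted p = 0.43; 2 higher, 2 lower), with allene oxide synthase, of jasmonate synthesis, at log2 -1.68 (adjusted p = 0.148). Benzoxazinoid synthesis had a median of -0.23 over 6 genes (adjusted p = 0.43; 2 lower), with indole-3-glycerol phosphate lyase at -1.74 (adjusted p = 0.276). That value rests on loop 1, with -3.82 in loop 1, -0.38 in loop 2, -0.69 without backslope plot 1 and -2.41 without backslope plot 2. Defence and pathogenesis-related genes had a median of -0.031 over 113 genes (adjusted p = 0.638; 3 higher, 2 lower), with a chitinase at -1.28 (adjusted p = 0.114). Nitrogen uptake and assimilation had a median of -0.024 over 40 genes (adjusted p = 0.846; 3 higher, 3 lower), with uroporphyrinogen decarboxylase, of the tetrapyrrole pathway that also makes siroheme, at 0.52 (adjusted p = 0.18). Sulfate and other ion uptake had a median of 0.022 over 38 genes (adjusted p = 0.683; 4 higher, 2 lower), with a sulfate transporter at 0.66 (adjusted p = 0.229). Starch and sucrose metabolism had a median of -0.016 over 81 genes (adjusted p = 0.592; 4 higher, 6 lower), with granule binding starch synthase II at -1.27 (adjusted p = 0.0927). Ethylene genes had a median of -0.0029 over 46 genes (adjusted p = 0.852; 2 higher, 4 lower), with an ethylene-inducible protein at 0.72 (adjusted p = 0.106). The called factor3 probe (MZ00026596) is not counted there, since a brighter probe at 0.23 (MZ00042351, adjusted p = 0.556) stands for its gene, and the annotation of the EREBP-like protein does not match the words of that list. Cytokinin and gibberellin genes had a median of -0.014 over 40 genes (adjusted p = 0.846; 2 higher, 3 lower), with pseudo-response regulator 1 as the member with the smallest p here too. It is a clock gene that the words of this list also match, so it does not report on these hormones. Histones and cell cycle genes had a median of 0.037 over 106 genes (adjusted p = 0.43; 8 higher, 2 lower), with proliferating cell nuclear antigen at -0.46 (adjusted p = 0.21), and at -0.30 without backslope plot 1.

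Cell wall genes had a median of -0.058 over 127 genes (adjusted p = 0.43; 2 higher, 7 lower unadjusted), with a xyloglucan endoglucanase, which loosens walls, at log2 -0.67 (adjusted p = 0.0927). Wax, cutin and lipid transfer genes had a median of 0.026 over 24 genes but a test on the lower side (adjusted p = 0.852; 0 in either direction). Glossy15, a regulator of juvenile leaf wax, stood at -0.21 (adjusted p = 0.448). Phloem and vascular markers had a median of -0.017 over 6 genes (adjusted p = 0.846; 0 in either direction), with a thioredoxin of phloem sap at -0.27 (adjusted p = 0.457). Root markers had a median of 0.11 over 10 genes (adjusted p = 0.43; 1 higher), with a nicotianamine aminotransferase at 0.33 (adjusted p = 0.344). Tassel, pollen and seed markers had a median of -0.0074 over 86 genes, a mean of 0.0077 and a test on the higher side (adjusted p = 0.924; 10 higher, 1 lower). An alpha zein, a seed storage protein, stood at 0.46 (adjusted p = 0.127). In these lists too no member passed in limma over all probes or adjusted over the list alone. Epidermis and guard cell markers had 3 measured genes with a median of -0.048, too few to test.

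The comparison of the site codes asked how far plots within the summit/shoulder class differ. Thiazole biosynthetic enzyme 1-2 stood at log2 2.82 over the backslope in plots of code 13013 (SE 0.30) and 2.57 in plots of code 306 (SE 0.30), and ZF1 at -2.64 (SE 0.30) and -2.02 (SE 0.30). Between the codes 0 probes passed in limma, with 1302 higher and 863 lower in 13013 at an unadjusted p under 0.05 and a smallest adjusted p of 0.607, so no gene is named for this contrast. Against the same backslope plots, 24 probes were higher and 48 lower for code 13013 and 0 passed for code 306 in limma (1272 higher and 1298 lower unadjusted). With no filter on dim probes the counts were 119 and 6. Since the difference between the codes passed at no probe, these counts do not show that the codes differ in effect. The 72 calls of code 13013 became 0 without backslope plot 1 (2823 unadjusted) and 11 without backslope plot 2. They became 2, 1, 40, 41, 168 and 3 without summit/shoulder plots 1 to 6 in turn. Code 306 gave 15 without backslope plot 3.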

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

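The test on shares of photosynthetic cells and the sorting of splits by position were chosen only after the results were seen, and the other tests in this part were planned. Among 95 sets of plot values, 2 had a plot far from the others by Dixon's ratio, where chance gives 4.75. For GST 24 (MZ00042425) summit/shoulder plot 6 stood at log2 -1.18 and the other 5 at -2.30 to -1.89 (ratio 0.632). For a purple acid phosphatase (MZ00046532) plot 5 stood at -0.15 and the others at -0.57 to -0.43 (ratio 0.667). In both genes all 6 plots kept the sign of the fitted difference, and no explanation was tested.

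For the fall of light-reaction transcripts (median -0.23), intensity-dependent normalization as the cause is argued against by 10000 random lists matched on intensity, none of which had a median as low (0.01%, the smallest such draws can give). A single loop or its scan batch is argued against because the median lay below all but 2.5% of matched lists in 3 of 3 loops. Carbon fixation genes did not fall alike, and their median of 0.0036 differed by 0.23 from that of the light reactions (permutation p = 0.00172, 2-sided, 100000 permutations over genes, which are not independent). This speaks against a smaller share of photosynthetic cells as the whole cause only as far as that list reports such cells. It also holds members that need not, such as a non-photosynthetic NADP-malic enzyme, so the test does not decide the question. Of 27 ways of setting 1 plot of each loop apart, 2 gave a p as small (smallest other 5.75e-09), so the count does not exclude chance. That other split set 2 backslope plots apart and so carries part of the position contrast. In the 12 splits with 1 backslope plot among the 3, where the contrast cancels, the list's p ran from 0.0924 to 0.848. There a position difference adds to the residual and can raise p, so these values are partly built in and do not speak against chance. The drought difference in the title stays open and was not tested apart from position.

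The rise of ribosomal protein transcripts (median 0.22) was weighed next. None of 10000 intensity-matched lists had a median as high (0.01%), which argues against intensity-dependent normalization, and 3 of 3 loops lay above all but 2.5% of matched lists, which argues against a single loop or its scan batch. Of 27 ways of setting 1 plot of each loop apart, 2 gave a p as small (smallest other 9.95e-15, in a split that keeps all 3 backslope plots together). In the 12 splits where the position contrast cancels, 8 gave a p under 0.05, the smallest 4.45e-06, so these genes also move together between plots apart from position. Chance is not excluded, and a difference in growth or water state of the plots could add to it and was not tested.

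Over the whole array the true split called the most probes, 95, which makes chance less likely without excluding it. It was 1 of 54 different contrasts that could be fitted beside the loops (81 splits, 54 of them in pairs with the same contrast). It was also 1 of 27 with 1 plot of each loop apart. Such sets can give no share smaller than 1 of 54 and 1 of 27. The highest count of any other split was 12 in both sets. At an unadjusted p under 0.05 the true split gave 3438 and was 1 of the 27, with 3150 as the highest other, while among the 54 contrasts it was 1 of 2 as high and the other reached 4127. For the number of lists called, 4 of the 27 gave as many as the true 4, with 6 as the highest other, so chance was not excluded by that count. The 3 other splits with as many carry part of the position contrast, and the 12 where it cancels called at most 3 lists. In those 12 a position difference adds to the residual, so fewer calls are partly built in. For each comparison of site codes the 10 splits of its 6 plots into 3 and 3, summit/shoulder plots alone or with the 3 backslope plots, are too few to tell. The real counts were 0 between the codes (10 of 10 splits as high), 72 for code 13013 against the backslope (1 of 10) and 0 for code 306 (10 of 10; 2570 unadjusted in limma), with 0 as the highest other in each.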

How the results depend on the processing

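The alternatives on array 6 and on list members were added after seeing the data, and the others were planned. Of 2359 pairs of a named gene and a setting, 2356 kept the sign, but calls of single genes depended on which plots were in. The count of 95 probes was 91 with no background subtraction, 69 with an offset of 0, 96 with print-tip loess, 72 with median centring, 105 with no filter, 117 with all negative spot marks out, 118 with trended and robust variances and 90 with the shifted probes of array 6 out. It was 31 (1253 unadjusted, 2 lists) with both channels above background on all 9 arrays, where fewer probes were tested. Array-level log ratios gave 653, by treating technical repeats as independent. Single-channel values gave 42 with the loop as a block (1994 unadjusted) and 5 without it (1206 unadjusted), so the calls need the pairing by loop. The authors' scores gave 36 (1231 unadjusted), on the probes they list. An adjusted p of 0.10 gave 364, and sample weights gave 717 (5330 unadjusted), with weights from 0.397 for summit/shoulder plot 5 to 2.36 for plot 1. With an estimated correlation 0 of 31 lists passed.

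Leaving out 1 plot each gave 0 to 389 probes (2107 to 5069 unadjusted) and 2 to 5 lists. The values were 0 without backslope plot 1 (2107 unadjusted) or 2 (2542 unadjusted), 168 without backslope plot 3, 1, 35, 16 and 389 without summit/shoulder plots 1, 2, 4 and 5, and 2 lists without backslope plot 2. Without loops 1, 2 and 3 they were 0 (1688 unadjusted), 12 and 164. Within loops 1, 2 and 3 they were 209, 63 (1227 unadjusted) and 0 (1349 unadjusted), each on 1 residual degree of freedom. Against the backslope, code 13013 gave 40 with no background subtraction, 119 with no filter and 0 to 168 with a plot left out, and code 306 gave 6 with no filter and 0 to 15 with a plot left out. Between the codes every setting run gave 0 in limma, with 1100 to 2973 unadjusted. The signs that turned were those of cytochrome P450 71C1 with the authors' scores (0.036) and, within loop 3, of glutamine synthetase (0.026) and an arabinogalactan-like protein (0.22). Except where fewer probes or plots or repeats taken as independent explain it, the cause was not tested.

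Ribosomal and light-reaction lists passed in every setting in which lists were tested with the preset correlation (they were not tested with sample weights), with medians of 0.19 to 0.26 and -0.28 to -0.21 when 1 plot was left out. The phosphate list lost its call in 3 settings with that correlation, 1 of them loop 3 alone with its 1 backslope plot, and the phenylpropanoid list in many, among them the authors' scores (adjusted p = 0.416) and all negative spot marks out (0.0979). Between 29.9% and 57.7% of probes stood above background in the red scan, which limits what dim probes can show.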

Other observations

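The time-of-day test below was chosen only after the result was seen, and the genes in this part were chosen after their values were seen. A probe for LHY (MZ00014272), a clock transcription factor that peaks at dawn, was 2.39-fold lower on the summit/shoulder (log2 -1.26, SE 0.19, adjusted p = 0.0413) in 6 of 6 plots. Other LHY probes stood at -1.55 (MZ00036336, adjusted p = 0.275) and 0.18 (MZ00023854, adjusted p = 0.615). A probe annotated with the Arabidopsis locus AT3g20810 (MZ00030647), whose product is a clock-associated demethylase expressed in the evening, was higher (log2 0.94, SE 0.15, adjusted p = 0.0444).

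A candidate explanation for LHY is that leaves of the position classes were collected at different times of day. Of 5 other clock genes, taken as peaking later in the day, the median was 0.43, but this decides nothing. Pseudo-response regulator 1 at 0.68 and gigantea at 0.44 had been seen before the test was chosen. The 3 not seen before were a Gigantea-like protein at 0.43, a pseudo-response regulator protein at -0.12 and pseudo-response regulator 73 at -0.17, whose class peaks earlier in the day. Collection times are not given in the sources used here, so the time of collection and a shift of the clock by the water state both stay open.

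Further called probes outside the naming rule were lower for MAP kinase 6 (log2 -1.32), an SRC2-like protein (-1.86), a kelch-repeat F-box protein (-1.51) and an RPT2-like protein (-1.19). The RPT2-like probe was above background in 6 of 12 summit/shoulder hybridizations, so its size is uncertain. Of 65 genes with a called probe, 34 had another probe tested and 6 had at least 2 called. Among 61 uncalled probes of those genes, 41 had the direction of the called probe. The probes for ribosomal protein S4 and XP-D gave near-equal differences in each plot measured, at -1.81 and -1.87 in plot 1, -3.23 and -3.31 in plot 2, -2.69 and -2.52 in plot 4 and -2.49 and -2.42 in plot 5.

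From the sums of each loop's 3 log ratios, the SD of a log ratio between hybridizations had a median of 0.23, and the residual SD between plots was 0.19. A dye effect that differed between loops would be counted in the 0.23. Hybridization noise of that size would give 50.6% of the residual variance. Across probes the differences of the loops correlated at 0.378 (loops 1 and 2), 0.433 (1 and 3) and 0.226 (2 and 3), with 60.5%, 60.9% and 55.5% of probes on the same side. Of the 95 called probes, 89 are among the spots that carry a score in the authors' table, as are 14097 of the 26777 tested.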
